A study of Mus musculus with 2 samples.

How the data were processed

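Droplet single-cell RNA sequencing had been done on mouse D3 embryonic stem cells on day 6 of cardiomyocyte differentiation, with 1 control and 1 Zbtb16 knockout library. Per the labels' protocols, cells were released with trypsin, strained and prepared with an MGI DNBelab C Series kit, and libraries were read on a DNBSEQ instrument. The deposited matrices hold raw UMI counts per gene and barcode, and per the file headers they were written by Cell Ranger 4. Per the submitters' processing notes, Cell Ranger and R 4.1.1 were used, and both GRCm39 and mm39 are named as the genome build. The barcodes have 16 bases, as Cell Ranger writes them, and how a DNBelab library was brought to that form is not given in the sources used here. Both matrices list the same 32285 features and were deposited unfiltered, with 2934307 control and 2775689 knockout barcodes. The deposited feature and barcode lists served only as names.

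Cells were called in each library by an order-of-magnitude rule, which kept barcodes with at least 10% of the UMIs at the 99th percentile of the top barcodes. The minimum came to 15059 UMIs in the control and 10953 in the knockout. At least 500 genes and at most 10% mitochondrial UMIs were required, which removed 24 control and 64 knockout barcodes. Scrublet (in scanpy 1.11.5, expected rate 6%) marked 0% and 0.0104% of cells, which means that it did not work here, so no doublets were removed. The kept cells held 94.8% of the control library's UMIs and 96.6% of the knockout's.

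UMIs were summed over cells of each library and turned into CPM, and ratios were taken of CPM plus a prior of 1. Sums carry exact Poisson intervals, shares exact Clopper-Pearson intervals, and list medians an interval from 200 Poisson resamples of the sums. The method was tested on simulated data for the all-cell sums: of 200 genes changed by 2-fold among 9972, 100% passed 1.5-fold in the right direction, 0% of the unchanged genes did, and 2 of 38 lists lay outside the 2.5th to 97.5th percentile. Both simulated libraries were Poisson counts drawn from 1 pooled profile at full depth. These rates therefore cover counting error only, and say nothing of differences between libraries, cultures or cell makeup. The 38 gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. List members count as measured at 5 CPM or more in either library, and a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Named genes are the 12 largest ratios in each direction among genes with at least 50 CPM in the all-cell sums, without predicted, ribosomal protein or mitochondrially encoded genes, and the 8 largest in each direction within a class. For lists they are up to 4 members by mean CPM and 2 by size of ratio, and Zbtb16, Igf2bp1, Igf2bp2 and Igf2bp3 always. The rule spoke of the 3 classes with the most cells, but only 2 had at least 100 cells in each library and were compared within. The genes whose shares of cells were thinned were chosen after their values were seen.

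Cells of both libraries were clustered together without batch integration, on log-normalised counts of 2000 variable genes without Zbtb16 or mitochondrial genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2). A cluster was named for a marker list with at least 3 genes, and more than any other list, among its top 10 genes at 20 CPM or more by fold over the median of the other clusters. This reference was chosen after it and the fold over all other cells had both been seen on the real clusters. The other reference left clusters 1, 3, 4, 6 and 11 unnamed, and its shares are among the alternatives. Free RNA was read from barcodes with 10 to 100 UMIs. A high estimate of its share in a class is called the largest share below. It used genes outside the cardiomyocyte list with at least 100 CPM in those barcodes. For each gene the upper limit of class CPM was divided by free RNA CPM, and the median of the 10 lowest values was taken. The lowest of the 10 would give a smaller share, so the median can exceed what the class allows. For phase calls and shares of cells with a UMI, each cell was thinned to the 20th percentile of depth.

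Transcript length and GC content came from the longest coding transcript of each gene, or the longest of any kind where none was coding, in GENCODE M21, on assembly GRCm38, matched by gene identifier for 99.97% of genes at 5 CPM or more. No coordinates are given because that assembly is not the one in the notes. Ratios were corrected by lowess trends on length and then GC (statsmodels 0.14.6). Alternatives covered the UMI, gene and mitochondrial limits, doublet scores, edgeR 4.0.16 TMM scaling, equal weight per cell, the prior, the filter on low values, resolution, number and scaling of variable genes, and thinning depth. Others were added after the data were seen: the other cluster reference, the length and GC correction, the subtraction of free RNA, and sums without some clusters or cells. Library, culture and knockout clone cannot be told apart with 1 library per group.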

Results

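Single-cell RNA sequencing compared mouse D3 embryonic stem cells with a Zbtb16 knockout of the same line on day 6 of cardiomyocyte differentiation, the stage of the cardiovascular progenitor. Zbtb16 encodes a zinc finger transcription factor. The stated purpose was to find which subpopulation depends on Zbtb16 at that stage. There were 2 libraries, 1 per group, so no difference has a replicate check and none was tested. Every interval given is an exact or resampled 95% interval that covers counting error only. A UMI is a molecular identifier that marks 1 captured RNA molecule, and CPM is a gene's UMIs scaled to the same total in each library. The control library held 308465930 UMIs and the knockout library 357324373. After filtering, 6353 control cells remained with a median of 37329 UMIs and 6392 genes, against 9609 knockout cells with a median of 30262 UMIs and 5924 genes.

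The targeted gene was measured first. Zbtb16 stood at 22.2 CPM in the control library (95% interval 21.7 to 22.8, 6507 UMIs) and at 0.991 CPM in the knockout library (0.889 to 1.10, 342 UMIs), a log2 ratio of -3.55. The deleted part of the gene is not given in the sources used here, so a 3' count checks the label only where the deletion lowers the transcript. The remaining knockout UMIs were unevenly spread over cell classes. In endoderm-like cells of the knockout library Zbtb16 stood at 10.2 CPM (8.49 to 12.2, 120 UMIs in 211 cells), against 32.7 CPM in those of the control library. In endothelial-like cells of the knockout library it stood at 0.145 CPM, from 3 UMIs in 423 cells, against 19.2 CPM in the control.

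The sums over all cells asked how the whole culture differed. Genes of the cardiac muscle fibre were far lower in the knockout library. All 16 measured members of the cardiomyocyte list were at least 1.5-fold lower, with a median log2 ratio of -3.46 (-3.51 to -3.42). Myl7, an atrial myosin light chain, stood at 817 CPM in the control and 11.4 CPM in the knockout. Tnnt2, cardiac troponin T, stood at 343 against 21.3 CPM, Actc1, cardiac actin, at 173 against 7.02 CPM, Ttn, titin, at 289 against 10.6 CPM, and Myl4 at 163 against 4.64 CPM. Tnni1 had the smallest difference among the named members, at 424 against 110 CPM. Without the cardiomyocyte-like clusters, in both libraries, the list median was -1.93.

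Transcription factors and signals of heart progenitors were lower as a group, with exceptions. Of 18 measured cardiac progenitor genes, 11 were at least 1.5-fold lower and 2 at least 1.5-fold higher, with a median of -1.17 (-1.20 to -1.14). The direction depended on which cells were summed: the median was -0.58, under 1.5-fold, without the cardiomyocyte-like clusters, and 0.53 without the unnamed clusters too, which left 494 control and 8594 knockout cells of different makeup. Both removals were chosen after seeing the data. Mef2c stood at 292 CPM in the control and 38.2 CPM in the knockout, Gata6 at 396 against 191 CPM, and Hand2 at 246 against 131 CPM. Sfrp5, a secreted Wnt antagonist of early heart progenitors, stood at 94.7 against 1.17 CPM. Hand1 went the other way, at 646 CPM in the control and 1247 CPM in the knockout, and Bmp4 stood at 181 against 269 CPM. The median was -1.36 over 8 genes of the first heart field and juxtacardiac field and -1.62 over 9 genes of the second heart field. Nkx2-5 stood at 14.96 against 1.37 CPM, Smarcd3 at 132 against 48.6 CPM, Hoxb1 at 157 against 23.4 CPM and Nr2f2 at 73.0 against 23.1 CPM. Several genes belong to more than 1 of these lists. The median of each of these 4 cardiac lists lay below all 10000 random lists matched on expression, which describes these libraries only.

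Matrix and mesenchymal genes were higher in the knockout library. Of 12 measured mesenchymal and fibroblast genes, 7 were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of 0.84 (0.81 to 0.86). Without the cardiomyocyte-like clusters this median was 0.58, under 1.5-fold. Postn, a matricellular protein, stood at 19.2 CPM in the control and 160 CPM in the knockout, Col1a1 at 43.6 against 194 CPM and Fn1, fibronectin, at 363 against 940 CPM. Twist1 was lower, at 279 against 139 CPM, and Col3a1 differed little, at 183 against 197 CPM. Of 21 extracellular matrix genes, 13 were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of 0.82. After correction for trends on transcript length and GC content the mesenchymal median was 0.63 and the matrix median 0.77. Smooth muscle genes split: Acta2 stood at 597 against 960 CPM and Cald1 at 376 against 701 CPM, while Myocd, a coactivator of muscle genes, stood at 26.1 against 1.06 CPM. The smooth muscle median was 0.03.

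**Figure D1:**
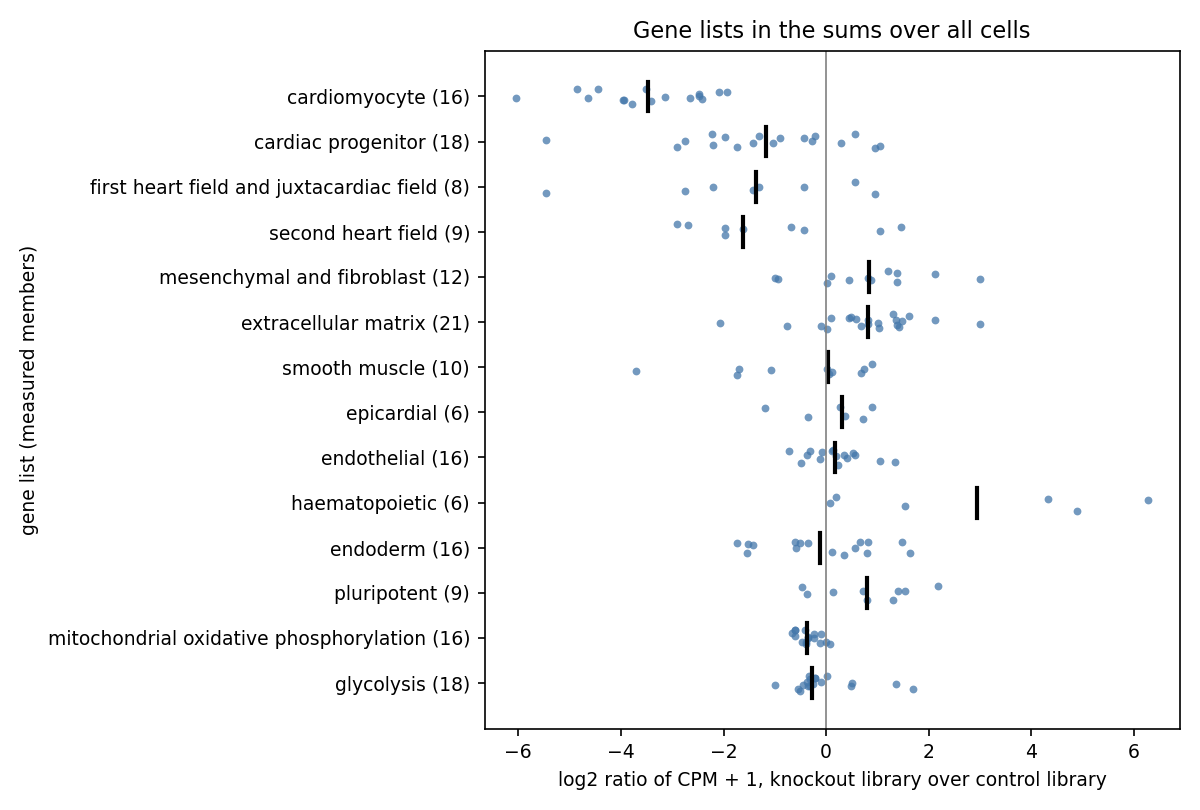
Each point is 1 measured gene of a list fixed before the data were examined, placed by the log2 ratio of its CPM plus 1 in the knockout library over the control library, on the horizontal axis. Black bars mark list medians and numbers in brackets count measured genes; all 16 cardiomyocyte genes lie left of 0, and the mesenchymal and matrix medians lie at 0.84 and 0.82.

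Among 3716 genes with at least 50 CPM in either library, 531 were at least 1.5-fold higher in the knockout library and 170 at least 1.5-fold lower, as counts by size. The log2 ratio followed transcript length across 10285 genes, with a Spearman rho of 0.452, and GC content with a rho of -0.278, where genes are not independent replicates. Its median was -0.19 for genes with transcripts of up to 1992 bases and 0.31 for those of at least 4750 bases. Correction for both trends, chosen after seeing the data, gave 297 higher and 166 lower genes. The 12 largest ratios in the lower direction belonged to Myl7, Sfrp5, Myl4, Ttn, Actc1, Pgam2, Mest, Rbm24, Tnnt2, Unc45b, Smyd1 and Ccdc141. Mest, an imprinted gene of mesoderm, stood at 1620 CPM in the control and 95.9 CPM in the knockout. Smyd1, a methyltransferase needed for heart muscle, stood at 71.4 against 6.01 CPM, and Rbm24, a muscle splicing factor, at 134 against 7.16 CPM. The 12 largest in the higher direction were Hba-x, Postn, Ahnak, Lrp2, Lama4, Tgfbr3, Man2a1, Col1a1, Nup62cl, Nrk, Igf2 and Cobll1. Igf2, an imprinted growth factor, stood at 563 CPM in the control and 2338 CPM in the knockout, and Ahnak at 203 against 1123 CPM. Embryonic globin Hba-x had 1 UMI in the control and 26485 in the knockout, a log2 ratio of 6.28 with the prior. Without the prior the ratio of CPM was 22444, with a counting interval of 4028 to 886534. Hba-x leads cluster 18, which held 38 knockout cells, and the interval treats UMIs as independent.

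The study's title names IGF2BP3, an RNA-binding protein that stabilises transcripts, and the 3 genes of this family were read by name. Igf2bp3 stood at 184 CPM in the control (182 to 185) and 212 CPM in the knockout (210 to 213), a log2 ratio of 0.21. Igf2bp1 stood at 211 against 318 CPM and Igf2bp2 at 141 against 140 CPM. After the length and GC correction the log2 ratios of Igf2bp3 and Igf2bp1 were -0.03 and 0.21. Within endothelial-like cells Igf2bp3 stood at 173 against 194 CPM, and within endoderm-like cells at 164 against 189 CPM. Only 1 of 15 genes that write, erase or read the RNA mark m6A was at least 1.5-fold higher and none at least 1.5-fold lower, with a list median of 0.06. After the correction none of the 15 passed 1.5-fold and the median was -0.079. These are RNA levels and carry no measure of transcript stability or of protein.

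Metabolic lists differed by smaller amounts. Genes of mitochondrial oxidative phosphorylation had a median of -0.38 over 16 genes, with 4 at least 1.5-fold lower and none higher, and Atp5b stood at 699 against 506 CPM. After the length and GC correction the median was -0.21, with 1 gene at least 1.5-fold lower, and the 13 mitochondrially encoded genes had an uncorrected median of 0.26. Glycolysis genes had a median of -0.28, or -0.17 after the correction, while the glucose transporters Slc2a1 and Slc2a3 stood higher in the knockout, at 614 against 1586 CPM and at 137 against 442 CPM. Of 13 measured Hox genes, which pattern the body axis, 5 were at least 1.5-fold higher and 4 at least 1.5-fold lower. Hoxb1 and Hoxb4 had log2 ratios of -2.69 and -0.83, Hoxb2 -0.52, which is under 1.5-fold, and Hoxb6 and Hoxc8 0.65 and 2.52. Hoxc8 is among the leading genes of unnamed cluster 8, which held 0.456% of control and 8.47% of knockout cells. The list median was -0.43.

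Clusters addressed the subpopulation question. Joint clustering gave 18 clusters, and 14 of them held at least 90% cells of 1 library. Those 14 held 92.1% of the 15962 cells, so such a cluster may be its library and not a cell type. Clusters 6, 9 and 13, named cardiomyocyte-like, held 2617 control cells and 9 knockout cells, and clusters 1, 2, 3, 4 and 11, named mesenchymal-like, held 61 and 7702. Their defining genes are genes that differ between the libraries, and the boundary moved with the settings. The cardiomyocyte-like share differed by -41.1 percentage points here and by between -19.7 and -76.7 under other settings. With genes scaled within each library it was -26.8. The mesenchymal-like share differed by 79.2 points here and by between 17.97 and 80.5 under the other settings that named such a cluster. Resolution 2.0 named none. Unnamed clusters 5 and 10, with 1436 and 752 control cells, had 2 mesenchymal markers among their leading genes, 1 short of that name. Unnamed clusters held 51.0% of control cells and 10.5% of knockout cells.

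The share differences of 4 smaller classes moved beyond their counting intervals only with at most 5% mitochondrial UMIs and, for endothelial-like cells, also with a doubled UMI minimum. Endothelial-like cells made up 4.42% of the control library (3.93 to 4.96) and 4.40% of the knockout library (4.00 to 4.83), a difference not detectable at this number of cells. Endoderm-like cells made up 1.89% (1.57 to 2.25) and 2.20% (1.91 to 2.51), whose intervals overlap. Pluripotent-like cells, with Pou5f1, Utf1 and Dppa5a among their leading genes, made up 0.504% (0.345 to 0.710) and 2.29% (1.9998 to 2.61). Haematopoietic-like cells, led by embryonic globins, numbered 38 in the knockout library, 0.395% (0.280 to 0.542). The control library had 0 of 6353, which allows a share of up to 0.0472% by a limit of 3 counts and 0.0580% by the exact interval.

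**Figure D2:**
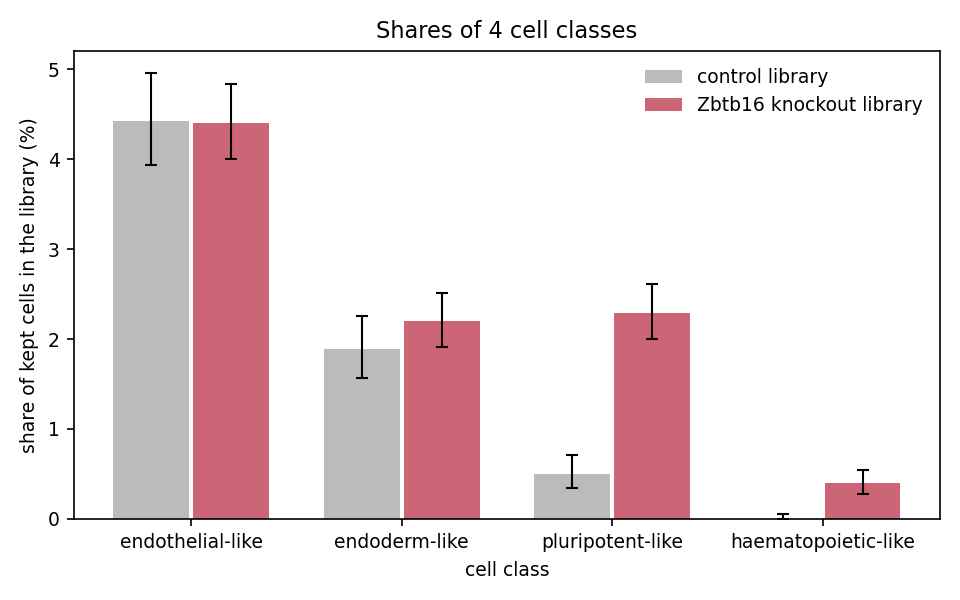
Bars give the share of kept cells in each library, in percent, for 4 cell classes on the horizontal axis, and error bars are exact 95% intervals for counting error. The endothelial-like bars stand at 4.42% and 4.40%, while the pluripotent-like bars stand at 0.504% in the control library and 2.29% in the knockout library.

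Endothelial-like cells showed whether the differences reached a class of equal share. The class held 281 control and 423 knockout cells, but cluster 16 held 230 of the control cells and cluster 12 held 422 of the knockout cells. Endothelial identity genes had a median of 0.00 over 18 genes. Genes of this same list gave clusters 12 and 16 their name, 7 in each, so a level median was partly set by the naming. Kdr, a VEGF receptor, stood at 301 against 538 CPM and Egfl7 at 782 against 547 CPM. Lower in the knockout were Mest, at 2029 against 161 CPM, Foxc2, at 87.7 against 17.6 CPM, the gap junction gene Gja4, at 50.5 against 11.7 CPM, and Smad6, an inhibitor of BMP signalling, at 60.7 against 14.8 CPM. Higher in the knockout were Igf2, at 479 against 2092 CPM, Nrp2, at 71.8 against 241 CPM, and the linker histone gene Hist1h1e, at 45.7 against 198 CPM. All 10 measured cardiomyocyte genes were at least 1.5-fold lower, with a median of -3.10. Of the control cells' UMIs for that list, 70.2% lay in the 10% of cells with the largest share of them, and without those cells in either library the median was -1.35. It was 0.10 once the largest free RNA share, a high estimate of 5.61% in the control and 5.20% in the knockout, was subtracted as well. The list then still summed to 62.7 CPM in the control against 6.82 CPM in the knockout, but 2 of the 10 genes were at least 1.5-fold lower and 3 at least 1.5-fold higher. The cardiac progenitor median in this class was -0.65, but it was 0.061 once the cells with the top 6% of doublet scores were removed.

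Endoderm-like cells, all in cluster 14, held 120 control and 211 knockout cells. Mest stood at 356 against 6.31 CPM, Apoa1, an apolipoprotein, at 210 against 47.8 CPM and the transcription factor gene Hhex at 96.9 against 20.6 CPM. Higher in the knockout were Pgap1, at 41.9 against 273 CPM, Hist1h1e, at 25.3 against 157 CPM, Fst, an inhibitor of activin, at 18.9 against 80.4 CPM, and Fabp3, at 55.1 against 225 CPM. Hist1h1e was thus higher in both classes, and in all cells too, with a log2 ratio of 1.95, so it is particular to neither class. Cardiomyocyte genes had a median of -2.25 over 14 genes, and 10 of them were at least 1.5-fold lower and 1 at least 1.5-fold higher. In the control, 75.9% of that list's UMIs lay in the top 10% of cells, and the median without them was -1.38, or 0.48 with the largest free RNA share, 7.81% and 7.54%, subtracted as well. Endoderm markers had a median of 0.30 over 22 genes, with 6 at least 1.5-fold higher and 7 at least 1.5-fold lower. In this list 4 genes gave cluster 14 its name, so the median was partly set by the naming.

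Shares of cells with a UMI were compared after each cell was thinned to 23607 UMIs, which left out 790 control and 2402 knockout cells. Myl7 was seen in 76.0% of control and 7.35% of knockout cells, and without thinning in 84.8% and 9.38%. In endothelial-like cells, whose median depths were 52197 and 38773 UMIs, the thinned shares were 65.0% and 1.30%. In endoderm-like cells, with median depths of 50330 and 45915 UMIs, they were 60.3% and 22.4%, so the knockout's overall share lay between those of the 2 classes, and no expression is read from it. Without thinning the shares were 80.1% and 3.78% in endothelial-like cells and 81.7% and 34.1% in endoderm-like cells. Phases were called from gene scores at the same depth, where free RNA enters too. G1 took 13.1% of control cells (12.2 to 14.04) and 10.7% of knockout cells (9.97 to 11.4), and without thinning 18.9% and 17.3%. The thinned difference of -2.45 percentage points was -6.50 with at most 5% mitochondrial UMIs. S phase took 38.4% (37.1 to 39.7) and 41.3% (40.2 to 42.5), and without thinning 35.95% and 38.6%, but with a doubled UMI minimum the thinned difference was -2.42 percentage points.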

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

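Among 2988 genes with at least 50 CPM in both classes, 220 were at least 1.5-fold higher and 30 at least 1.5-fold lower in the knockout library in endothelial-like and endoderm-like cells alike. Only 4 genes differed by that much in opposite directions, which is what singled them out after their values were seen, and the difference between classes was not tested. Sgk1, a stress-responsive kinase gene, stood at 219 against 66.8 CPM in endothelial-like cells and at 59.9 against 156 CPM in endoderm-like cells, a difference of log2 ratios of -3.07. Cyp26a1, which breaks down retinoic acid, stood at 95.2 against 28.3 CPM and at 29.1 against 64.7 CPM, a difference of -2.84. Lgmn, a lysosomal protease gene, stood at 83.6 against 42.2 CPM and at 494 against 830 CPM, a difference of -1.72. Col18a1, a basement membrane collagen, stood at 245 against 426 CPM and at 75.2 against 42.0 CPM, a difference of 1.62.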

How the results depend on the processing

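No paired analysis was possible because each group has 1 library and no result comes from a test. The alternatives without some clusters or cells, the subtraction of free RNA, the length and GC correction and the other cluster reference were chosen after seeing the data. For log2 ratios of at least 1.5-fold, 1415 of 1417 alternative values of named genes in all cells kept their direction, 448 of 448 of named genes within classes, 209 of 211 of list medians in all cells and 218 of 224 within classes. Part of this tally was fixed by construction or nearly so. A minimum of 1000 genes kept the same 6353 control and 9609 knockout cells. A prior of 5 CPM cannot change the sign of a gene's ratio, and TMM scaling moved log2 ratios by at most 0.017. Endoderm-like cells were too few for a comparison at 5% mitochondrial UMIs and without the top doublet scores, and resolution 2.0 named no mesenchymal-like cluster. For the values listed next, the cause was not tested.

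With the mean over cells of each cell's CPM, the cardiomyocyte, cardiac progenitor and mesenchymal medians were -4.03, -1.25 and 0.91, and the endothelial-like cells' cardiomyocyte median was -2.41. A prior of 5 CPM, which shrinks low genes by construction, gave -2.15, -0.96 and 0.75, Zbtb16 -2.19, and cardiomyocyte medians of -2.19 and -1.51 in endothelial-like and endoderm-like cells. No filter gave cardiomyocyte medians of -2.90 in all cells and -2.14 and -1.70 in the 2 classes. A 20 CPM filter gave -3.95, -3.87 and -3.33, and a cardiac progenitor median of -1.05. A doubled UMI minimum gave -2.92, -1.09 and 0.79. At 5% mitochondrial UMIs, which left 5088 control and 4683 knockout cells, the cardiomyocyte and mesenchymal medians were -3.52 and 0.75 and Zbtb16 -3.72. Length and GC correction gave -3.35, -1.10 and 0.63, Zbtb16 -3.75, 297 higher genes and -2.84 in endothelial-like cells. Without the 4 small classes, the cardiomyocyte and mesenchymal medians were -3.75 and 0.91 and Zbtb16 -3.75. Without cardiomyocyte-like clusters the 3 medians were -1.93, -0.58 and 0.58, the last 2 under 1.5-fold. Without the unnamed clusters too, the cardiomyocyte median was -1.64, over 494 control and 8594 knockout cells. Without the cells that 4000 variable genes place in cardiomyocyte-like clusters, the cardiomyocyte and cardiac progenitor medians were -1.82 and -0.32. Without the 10% of cells richest in cardiomyocyte UMIs the class medians were -1.35 and -1.38, with the largest free RNA share subtracted -2.23 and -1.92, and without the top doublet scores the endothelial-like one was -2.58.

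The cardiomyocyte-like share difference was -51.4 and -48.0 points at resolutions 0.5 and 2.0, -26.8 with scaling within each library, -76.7 with 4000 variable genes, -44.6 and -22.0 with the UMI minimum halved and doubled, -26.5 with the higher minimum for both, -27.2 and -23.5 at 5% and 20% mitochondrial UMIs, -26.1 without the top doublet scores and -19.7 with the other cluster reference. The mesenchymal-like one was 80.5 at resolution 0.5, 63.4 with scaling within each library, 17.97 with 4000 variable genes, 63.8 and 62.8 with the minimum halved and doubled, 72.7 with the higher minimum, 77.0 at 5% mitochondrial UMIs, 63.4 without the top doublet scores and 18.6 with the other reference. At 5% mitochondrial UMIs the endothelial-, endoderm-, pluripotent- and haematopoietic-like differences were 1.33, -0.896, 2.48 and 0.598, and the G1 difference -6.50. The endothelial-like one was -0.726 with the minimum doubled.

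Reversed were the cardiac progenitor median without the cardiomyocyte-like and unnamed clusters (0.53, from -1.17 in all cells), the endothelial-like and endoderm-like cells' cardiomyocyte medians with free RNA subtracted and without the richest 10% of cells (0.10 and 0.48, from -3.10 and -2.25), the germ cell median with equal weight per cell (-0.20), Klf2 without the 4 small classes (-0.042), Apob at 5% mitochondrial UMIs (-0.37), the endothelial-like cells' cardiac progenitor median without the top doublet scores (0.061) and their first heart field median at 20 CPM (0.067), the endoderm-like cells' primitive streak median with no filter (-0.0916) and epicardial median at 20 CPM (0.014), and the S phase difference with the minimum doubled (-2.42).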

Other observations

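The 3 patterns at the end were picked from values already seen, and so was the length and GC correction behind the medians of -3.35 and 1.14. The tests of fewer cardiomyocyte-like cells, of free RNA, of doublets and of both together were also chosen after values they bear on had been seen. The limits of the other tests were set before their own values were computed. The imprinted growth genes included some of the most abundant differences. Igf2 and Igf2r stood at 563 against 2338 CPM and 279 against 900 CPM, Peg3 at 1475 against 2522 CPM, and Plagl1, a regulator of other imprinted genes, at 1.70 against 19.2 CPM. Mest and Ndn stood lower, at 1620 against 95.9 CPM and at 210 against 119 CPM. Igf2r and Ndn lie outside the rule for named genes and were chosen after their values were seen. Cells that clustered with the other library did not take on its Mest and Zbtb16 levels. The 90 control cells in knockout clusters had Mest at 1917 CPM and Zbtb16 at 33.6 CPM (28.0 to 40.0). Both lay above their own library's 1620 and 22.2 CPM. The 29 knockout cells in control clusters had Mest at 74.0 CPM and Zbtb16 at 1.90 CPM (0.230 to 6.85). Their own library had 95.9 and 0.991 CPM. Igf2 lay between the libraries in both, at 1073 and 1591 CPM.

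Pluripotent genes had a median log2 ratio of 0.80 over 9 genes, with Dppa5a at 29.6 against 74.3 CPM and Sox2 at 4.33 against 23.2 CPM. The endoderm and endothelial lists had medians of -0.12 and 0.17. Cdx2, of posterior and trophoblast cells, stood at 1.84 against 14.9 CPM. Unnamed cluster 8, led by Lefty2, Hoxc10, Sox2, Hoxc8 and Cdx2, held 29 control cells and 814 knockout cells, 0.456% and 8.47%. Hypoxia genes in all cells split around a median of 0.23: Ndrg1 stood at 14.3 against 51.6 CPM and P4ha1 at 42.4 against 94.7 CPM, while Adm stood at 12.5 against 2.02 CPM. Their median was 0.78 over 9 genes in endothelial-like cells, with 6 at least 1.5-fold higher and 1 lower. In endoderm-like cells it was 0.53 over 8 genes, with 4 higher and 1 lower by that much. Immediate early genes had a median of -0.43, with Fosb at 51.3 against 17.96 CPM.

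Barcodes with 300 UMIs or more that lay under the UMI minimum were not used in any comparison. There were 2474 in the control, with a median of 73.2% mitochondrial UMIs, and 1432 in the knockout, with 62.2%. Per 100 kept cells that came to 38.9 and 14.9.

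The first pattern is that many genes were higher in the knockout library in all cells and in both compared classes: 188 of 2890 genes with at least 50 CPM in each. These 188 genes had a median transcript length of 5952 bases, against 2666 for all 2890. A length bias between the libraries may account for part of them, since length correlated with the log2 ratio across genes with a Spearman rho of at least 0.426 in both classes. A GC bias may also contribute, with a rho of -0.311 in the class where it was weaker; genes are not independent replicates. After correction 85 of the 188 were still at least 1.5-fold higher in all cells. The correction covers trends on length and GC only, so other technical differences may remain among these 85. Which share comes from RNA quality, library preparation or the knockout stays open.

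The second pattern is the low cardiomyocyte genes. A length or GC bias alone is argued against by the corrected median of -3.35, and a loss confined to clusters 6, 9 and 13, with no free RNA or doublets from them, by the median of -1.93 without them. Within endothelial-like and endoderm-like cells, free RNA alone is argued against by medians of -2.23 and -1.92 after its largest share was subtracted. Doublets in up to 10% of cells alone are argued against by medians of -1.35 and -1.38. In endoderm-like cells free RNA and doublets together may account for the difference, since both steps left a median of 0.48. The list then summed to 54.8 CPM in the control and 122 CPM in the knockout, with 1 of 14 genes at least 1.5-fold lower and 6 at least 1.5-fold higher. In endothelial-like cells both steps left a median of 0.10, but the list still summed to 62.7 against 6.82 CPM. Of its 10 genes, 2 were then at least 1.5-fold lower and 3 at least 1.5-fold higher. Part of the difference may thus remain there, though not across the list. The subtracted share is a high estimate that can exceed what the class allows, and negative values were cut off. Both steps together may thus take away too much. Removing the cells richest in the list would also remove true expression in them. A loss of cardiac cells beyond those clusters stays open, as do the knockout, a slower differentiation and a property of the clone: the median of -1.64 without the unnamed clusters too compares cells of different makeup, and unnamed cluster 7, with Smyd1, Rbm24 and Ttn among its leading genes, held 999 control and 10 knockout cells, but unnamed cluster 17, with Actc1 and Myh7, held 26 and 173.

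The third pattern is the imprinted genes. Of 13 measured, 8 differed by at least 1.5-fold in the all-cell sums. H19, Igf2, Igf2r, Peg3, Peg10 and Plagl1 were higher in the knockout library, and Mest and Ndn were lower. H19 had a log2 ratio of 0.67, or 0.81 after the length and GC correction. Differing shares of the named classes alone are argued against. In the all-cell direction the median log2 ratio of the 8 genes was 1.74 within endothelial-like cells, where all 8 passed 1.5-fold. It was 1.22 within endoderm-like cells, where 4 of 7 did. These medians were 1.89 and 1.77 with the largest free RNA share subtracted. The 8 genes and their directions came from the same data. Endothelial-like cells of the 2 libraries lay mostly in different clusters, so makeup inside that class was not held fixed. Over all 12 list genes measured in endoderm-like cells, 3 were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of -0.08. A length or GC bias alone is argued against by the 8 genes' corrected median of 1.14 and by 6 of the 13 still past 1.5-fold. But Peg3 and Peg10 fell under 1.5-fold after correction for transcript length and GC, from 0.77 to 0.34 and from 0.93 to 0.55. Such a bias may account for part of these 2. A difference in imprint between the 2 cell stocks is a hypothesis that these counts cannot test, and it would be confounded with the knockout.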
